A study of Colinus virginianus with 24 samples.

How the data were processed

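RNA from the liver and from the feather pulp (the living core of a growing feather) of Northern bobwhite quail, Colinus virginianus, was measured on 24 single-colour microarrays. The birds had been dosed with 2,6-DNT (2,6-dinitrotoluene, a nitroaromatic compound used in making explosives) at 0, 10 or 60 mg/kg/d. Each of the 6 combinations of tissue and dose held 4 arrays. The labels call the arrays biological replicates and give each a number from 1 to 4, but do not say whether a number marks a bird.

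Per the labels' protocols, RNA was preserved in a fixative, extracted on columns, checked for quality by electrophoresis and labelled with Cy3. Per the file headers, the scans were quantified with Agilent Feature Extraction 9.5.1.1, and each deposited file holds spot intensity values on a linear scale, among them a processed signal that is corrected for background and for spatial trends. Each array carried 15504 spots, of which 14968 were probes and 536 were control spots. Every probe was spotted once and had a length of 60 bases. The authors also deposited a table of values, in which each value is the fraction of an array's background-subtracted signal. Set against the scanner signals, its log2 values followed the background-subtracted signal of the same array with r = 1 on every array, values of that signal at or below 0 stood at 0 in the table, and direction and scale were thereby settled. The medians of its columns ran from 2.86e-06 to 7.36e-06. No centring of probes was seen in it.

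The probes carry names of contigs and sequencing reads only. A description other than unknown was given for 0 probes, and a genome coordinate for 0 probes. The files do not pair these names with genes, and no reference was used here. The gene lists fixed before the data were examined, which covered drug metabolism, lipid metabolism, stress responses, blood and feather markers and similar groups, could not be applied for that reason and have no result. The rule for named genes took probes with a gene name, and none qualified. In its place, and chosen after the values were seen, at most 2 probes that rose and 2 that fell are named for a comparison, as those with the largest change among the called probes whose treated arrays all lay on the same side of the control mean. Of 11710 contigs or reads, 3258 were represented by a probe in each orientation.

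The log2 processed signal of each array was reduced by the 75th percentile of its own probes. Spots that the scanner software marked as non-uniform or as outliers were then set to missing, and saturated spots were kept. A probe was tested if its signal was well above background on at least 3 arrays of 1 or more groups. Groups were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Dose comparisons were fitted on the 12 arrays of a tissue, and the tissue comparison and the tissue by dose interactions on all 24 arrays. Where a probe was not well above background, or was saturated, on every array of a group, its difference is given as a lower bound: the mean of the brighter group against the mean, per array, of the higher of the lowest signal well above background and the signal of the probe itself. Levels are log2 signals relative to the 75th percentile of the array and are not comparable between probes. Figures were drawn with matplotlib.

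Arrays were read on 3 slides of 8 arrays, each scanned separately, so that slide and scan are 1 factor. Of the liver arrays, slide 1 held only 2 arrays of the 60 mg/kg/d group, and slide 3 held 2 arrays of each dose. The remaining control and 10 mg/kg/d livers lay on slide 2. Feather arrays of every dose lay on slides 1 and 2.

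The replicate numbers were checked by correlating the deviations of arrays from their group means across probes. Liver and feather arrays of the same dose and number had correlations between 0.13 and 0.36 at 0 mg/kg/d and between 0.15 and 0.31 at 10 mg/kg/d. Arrays of the same dose and number were therefore treated as paired in an alternative fit with a replicate block and in the later tests by dose and number. The main fits used group means only and left this pairing out. At 60 mg/kg/d the correlations ran from -0.08 to 0.35, and only 1 of 4 was above 0.1. Over the brighter probes alone, 11 of the 12 pairs at all doses were above 0.1. Arrays of the same tissue and number at different doses had a median correlation of 0.02 and were not treated as paired.

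The alternatives tried were other normalizations and background corrections, other filters on dim probes, the slide or the replicate number as a block, the deposited table, other sets of arrays in the fit, leaving out each array in turn, a minimum fold change of 1.5, and the mean over the probes of a contig. The other background correction was normexp in limma with an offset of 50, followed by quantile normalization. For the deposited values, expressed as parts per 1000000, log2 was taken after adding 0.1. Keeping non-uniform spots, and fitting the dose comparisons of a tissue on all arrays with a slide block, were added after the data had been examined.

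The fits were tested on simulated data. For the liver comparison of 60 with 0 mg/kg/d, simulated over 11253 probes, 43 of 50 probes changed by 2 log2 units and 11 of 50 changed by 1 log2 unit were called, with 8 false calls. For the same comparison in feather pulp, simulated over 11579 probes, 39 of 50 and 17 of 50 were called, with 6 false calls. The number of arrays limits the precision.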

Results

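The data set described the transcriptional response of a wild bird to a munitions compound at 3 doses, in an internal organ and in a tissue that can be sampled without killing the bird. The signal of 65.2% to 87.1% of the probes was well above background, depending on the array. Between 129 and 294 probes per array were saturated, and between 32 and 1120 were set to missing as non-uniform. The array with the highest number of missing probes, feather pulp at 60 mg/kg/d replicate 4, also had the highest share of probes above background. Pairs of arrays of a group correlated, across probes, with medians of 0.966 in control liver, 0.969 in liver at 10 mg/kg/d and 0.944 in liver at 60 mg/kg/d. The lowest pair of the last group reached 0.919. In feather pulp, the medians were 0.961, 0.955 and 0.943 with increasing dose.

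Control liver and control feather pulp differed in close to every other probe. Of 12350 probes tested, 2889 were higher in liver and 3229 were higher in feather pulp (limma, adjusted p under 0.05). Thus 47.2% of the calls were higher in liver, while the deposited values gave 2024 higher in liver and 4331 higher in feather pulp, or 31.8%. Among the probes higher in liver, 1277 differed by at least 4-fold, as did 1173 of those higher in feather pulp. Contig9458 and Contig1_25669_R, named by their fitted differences toward liver, were saturated on all 4 control liver arrays and not well above background on any of the 4 control feather arrays. Saturation and background leave their rank among the probes unknown. Their signals in liver were at least 2577-fold and at least 2586-fold higher (limma, adjusted p = 1.22e-15 and 5.11e-15). In the other direction, Contig15086 and Contig3035 were well above background on the 3 feather arrays measured and on none of 4 liver arrays, and were at least 1579-fold and at least 1385-fold higher in feather pulp (limma, adjusted p = 7.13e-13 and 6.26e-16). These bounds rest on the background correction of the scanner software. With normexp correction and quantile normalization the fitted log2 differences were 9.65 for both liver probes, and -9.41 and -9.66 for the feather probes. All were smaller than the bounds. The normexp offset of 50 by itself shrinks differences from dim signals, so these values do not decide whether the bounds hold. The probe sequence of Contig9458 is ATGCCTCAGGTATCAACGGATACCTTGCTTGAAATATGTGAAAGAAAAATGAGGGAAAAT, and that of Contig3035 is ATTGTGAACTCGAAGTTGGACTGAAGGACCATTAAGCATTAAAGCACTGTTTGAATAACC.

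In liver, 60 mg/kg/d against 0 changed 605 of 11236 probes tested, of which 254 rose and 351 fell (limma, adjusted p under 0.05). At least a 2-fold change was found in 233 of the probes that rose and in 328 of those that fell. The probes that rose had a median log2 fold change of 1.83, and those that fell one of -1.505. The median log2 fold change of all probes tested was -0.12, so the changes are to be read against that shift. Scaling to the array median in place of the 75th percentile brought this median to -0.01, and 53.6% of the calls were then increases, against 42.0%. With quantile normalization 48.9% of the calls were increases, and with the deposited values 69.7% were.

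ERPU0F302FGZKI was not well above background on any control liver array and was so on all 4 arrays at 60 mg/kg/d, where its log2 signal was -0.85 ± 0.30 (SD, n = 4). Its increase was at least 12.96-fold (limma, adjusted p = 0.000397). Among the liver arrays, Contig1533 was likewise well above background only after treatment, on 2 of 4 arrays at 10 mg/kg/d and on 4 of 4 at 60 mg/kg/d, with an increase of at least 9.37-fold at the higher dose (limma, adjusted p = 0.00696). Both bounds rest on the background correction. With normexp and quantile normalization the fitted log2 changes of ERPU0F302FGZKI and Contig1533 were 2.33 and 2.35, below the bounds. Quantile normalization alone gave 5.30 and 5.17, from controls below background. The normexp offset of 50 by itself shrinks changes from dim signals, so the size stays unsettled. EQOT2SL02HECDK stood at 0.24 ± 0.72 (SD, n = 4) in control liver, at -2.33 ± 0.71 at 10 mg/kg/d and at -4.02 ± 0.49 at 60 mg/kg/d. Its log2 fold change at 60 mg/kg/d was -4.26 ± 0.42 (SE; limma, adjusted p = 0.000397), or -4.13 relative to the median of all probes. At that dose 3 of 4 arrays had it well above background, and with normexp and quantile normalization its change was -2.92. Contig5651 fell by 4.97 ± 0.90 on the log2 scale (SE; limma, adjusted p = 0.0102), from -0.12 ± 1.18 to -5.09 ± 1.96 (SD, n = 4), and 2 of 4 arrays at 60 mg/kg/d had it well above background, so the fitted size leans on readings at background. The probe sequence of ERPU0F302FGZKI is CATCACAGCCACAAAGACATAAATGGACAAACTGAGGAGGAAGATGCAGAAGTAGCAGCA, and that of EQOT2SL02HECDK is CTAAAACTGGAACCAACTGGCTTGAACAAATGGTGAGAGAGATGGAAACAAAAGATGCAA.

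**Figure D1:**
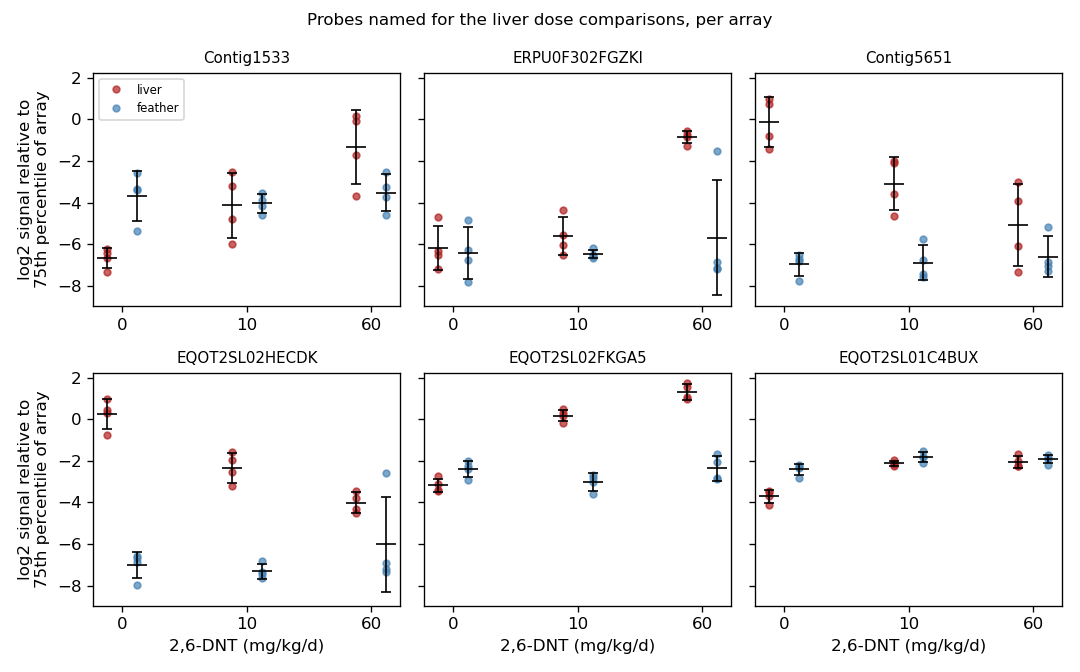
Log2 signal relative to the 75th percentile of the array (vertical axis) against dose of 2,6-DNT in mg/kg/d (horizontal axis) for the probes named in the liver dose comparisons, with 1 point per array, red for liver and blue for feather pulp, and black bars for mean and SD. EQOT2SL02FKGA5 rose from -3.17 in control liver to 0.17 and 1.31, while its mean in feather pulp stayed between -3.02 and -2.37.

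The slide bore on the number of calls in this comparison. With the slide as a fixed block in the fit of the 12 liver arrays, in which slide 1 holds 60 mg/kg/d arrays only, 17 probes were called, 5 higher and 12 lower. All of the 605 probes (100%) kept their sign in that fit, which shares its arrays with their choice. Their median change in the direction called was 1.48 on the log2 scale, against 1.63 without the block, and the median SE was 0.425, against 0.351. The calls thus ended with a larger error more than with a smaller change, and their number alone does not show an effect of the slide. Since the same arrays chose the 605 probes, their change was favoured to stay large, so its size does not clear the slide either. For EQOT2SL02HECDK the log2 fold change was -4.46 ± 0.53 with the block (SE; limma, adjusted p = 0.00840), with 1 of the 2 arrays of that dose on slide 3 well above background. Contig5651 and ERPU0F302FGZKI stayed called (limma, adjusted p = 0.0258 and 0.0152), but the first was below background on both of these arrays and the second in the controls, so no size is given. Contig1533 did not (limma, adjusted p = 0.0738): its fitted change, taken from a control below background, was 5.47 ± 1.09 with the block and 5.32 ± 0.84 without (SE), so its error had grown. Within slide 3, which held 2 liver arrays of each dose, 0 probes were called and 985 had an unadjusted p below 0.05 in limma, at a size of 2 against 2 arrays. With all 24 arrays in 1 fit, 831 probes were called without the slide block, of which 472 were among the 605. With it 577 were called, of which 383 were among the 605. In that fit feather arrays of all doses on slide 1 help to estimate the slide. The block takes the slide to act alike in both tissues, which was not tested. The fit also left out the pairing by dose and number. Single arrays mattered as well: 208 probes were called without liver at 60 mg/kg/d replicate 2 and 1554 without replicate 3, of which 339 rose and 1215 fell, or 21.8% increases, while leaving out control replicate 2, 3 or 4 gave 328, 285 and 280.

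At 10 mg/kg/d, 3 probes rose in liver and 0 fell, of 11251 tested, and 1119 had an unadjusted p below 0.05 in limma. EQOT2SL02FKGA5 rose by 3.34 ± 0.26 on the log2 scale (SE; limma, adjusted p = 8.19e-05), from -3.17 ± 0.32 to 0.17 ± 0.28 (SD, n = 4), and reached 1.31 ± 0.37 at 60 mg/kg/d. EQOT2SL01C4BUX rose by 1.59 ± 0.23 (SE; limma, adjusted p = 0.0346), from -3.70 ± 0.31 to -2.11 ± 0.12, and stood at -2.05 ± 0.29 at 60 mg/kg/d. The call of EQOT2SL02FKGA5 was kept in all 23 alternative settings, and that of EQOT2SL01C4BUX in 13 of 23. The sequence of the EQOT2SL02FKGA5 probe is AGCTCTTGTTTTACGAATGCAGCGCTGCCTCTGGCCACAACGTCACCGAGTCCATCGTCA. With the slide as a block 2 probes were called. Within slide 2 the count was also 2, and within slide 3 it was 0, with 537 probes at an unadjusted p below 0.05 in limma. Leaving out control replicate 2 or 3, or 10 mg/kg/d replicate 2, 3 or 4, left 1 call, while 6 were made without control replicate 4 and 13 without 10 mg/kg/d replicate 1. Of these 13, 3 rose and 10 fell. All 24 arrays in 1 fit gave 15 higher and 19 lower, and the replicate block by number 2 and 2, while quantile normalization gave 5 higher and 0 lower. The direction of the calls thus depended on the fit. Between 60 and 10 mg/kg/d, 54 probes were higher and 42 lower at the higher dose. The deposited values gave 62 higher and 22 lower. With the slide as a block 3 were called, and within slide 3 it was 0, with 737 at an unadjusted p below 0.05 in limma. Without liver at 60 mg/kg/d replicate 2 there were 4 calls, and without replicate 4 there were 322. Without replicate 3 there were 119, of which 34 were higher and 85 lower, so the balance of directions turned. Leaving out 10 mg/kg/d replicates 1, 2, 3 and 4 in turn gave 6, 5, 19 and 18.

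In liver, the changes at 10 and 60 mg/kg/d covaried by more than their shared controls gave. Across 11235 probes, which are not independent replicates, the log2 fold changes at 10 and 60 mg/kg/d correlated with r = 0.513. Since both use the same control arrays, simulated unchanged groups gave r = 0.499. The covariance was 0.193, against 0.0870 in the simulation, a difference of 0.106. With the controls split between the comparisons, r averaged 0.273 over 6 splits, from 0.113 to 0.401. In feather pulp, r was 0.549 against a simulated 0.501, the covariance exceeded the simulated one by 0.00287, and r averaged 0.0422 with the controls split. In liver, probes called at 60 mg/kg/d with 2 of the controls were judged at 10 mg/kg/d on the other 2. The change at 60 mg/kg/d was taken from those other 2 as well, so sign and share still carry a shared control error. Over 6 such splits, with 9 to 178 probes called, 60.7% to 91.4% had the same sign, and the median share of the higher-dose change was between 0.122 and 0.380.

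In feather pulp, limma called 0 probes at 60 mg/kg/d, of 11560 tested, and 399 had an unadjusted p below 0.05. At 10 mg/kg/d it called 0 of 11573, with 631 at an unadjusted p below 0.05, and between the 2 treated doses 0 of 11559, with 350. The median SE of a log2 fold change at 60 mg/kg/d was 0.296 in feather pulp and 0.319 in liver. With the slide as a block, 8 probes were lower at 10 mg/kg/d, while the other 2 comparisons kept 0 calls in limma, with 624 and 611 probes at an unadjusted p below 0.05. Within slide 1, which held 2 feather arrays of each dose, limma called 0 probes in each comparison, with 788, 779 and 718 at an unadjusted p below 0.05 in the order given. Slide 2 held 2 arrays at 10 mg/kg/d and 1 at each of the other doses, so the spread came from that pair alone and the lone arrays were assumed to vary like it. With single arrays in an arm, dose cannot be separated from array, so the calls on that slide are not read as effects of dose. There limma called 26 higher and 20 lower probes at 60 against 0 mg/kg/d, 82 higher and 66 lower at 10 against 0, and 2 higher and 3 lower at 60 against 10. Slide 3 held 1 array at 0 and 1 at 60 mg/kg/d, which leaves no spread for a test.

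The dose effect differed between the tissues for 57 of 12295 probes at 60 mg/kg/d, 31 with a more positive and 26 with a more negative change in liver (limma interaction, adjusted p under 0.05). EQOT2SL02FKGA5 had the smallest adjusted p, with a difference of 4.46 on the log2 scale (limma, adjusted p = 4.29e-06). Of the 57, 26 were well above background on at least 3 arrays of each of the 4 groups compared, 16 with a more positive and 10 with a more negative change in liver. Contig1533, EQOT2SL02HECDK and Contig5651 were called too, but were not well above background on any array of control liver, control feather pulp and feather pulp in that order, so the size of their difference is not known. The deposited values gave 35 more positive and 12 more negative changes, or 74.5% more positive, against 54.4%, while quantile normalization gave 67.0% and median scaling 70.4%. The slide as a block gave 43 calls. With arrays of the same dose and number as a replicate block there were 166, 87 more positive and 79 more negative. Without control liver replicate 3 or replicate 4 there were 4 calls each, and without replicate 1 there were 95. Leaving out liver at 60 mg/kg/d replicates 1, 2 and 4 gave 87, 13 and 121. Leaving out control feather replicates 1, 2, 3 and 4 gave 24, 17, 12 and 37, and feather at 60 mg/kg/d replicates 1 and 3 gave 13 and 21. At 10 mg/kg/d, 1 of 12329 probes differed, EQOT2SL02FKGA5, in the fit as designed and with either block.

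Probes were further grouped by tissue, with classes chosen after the data had been seen and taken from the 10 mg/kg/d arrays, which enter neither side of the comparison of 60 with 0. At 10 mg/kg/d slide 1 held feather arrays but no liver arrays, and it held livers at 60 mg/kg/d but no control livers. The classes are thus not free of the slide. Of 1164 probes at least 4-fold higher in liver than in feather pulp, 140 fell and 19 rose in liver at 60 mg/kg/d. Their median log2 fold change was -0.51. Of 784 probes at least 4-fold higher in feather pulp, 71 rose and 6 fell, with a median of 0.32. The remaining 9288 probes had 164 increases and 205 decreases and a median of -0.10. In a set test with preset correlation, over the probes with no missing spot, both classes stood apart from the other probes (camera in limma, adjusted p = 1.64e-09 and 3.92e-09). With an estimated correlation neither did (adjusted p = 0.109 and 0.192). With the slide as a block, the class medians were -0.60 and 0.35, and the adjusted p with an estimated correlation was 0.0390 for the liver-enriched and 0.316 for the feather-enriched class. Within slide 3 the medians were -0.62 and 0.33, and neither class stood apart with an estimated correlation (camera, adjusted p = 0.163 and 0.448). Without liver at 60 mg/kg/d replicate 3, the medians were -0.40 and 0.09, against -0.15 for all probes. There too neither class stood apart with an estimated correlation (camera, adjusted p = 0.220 for both).

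**Figure D2:**
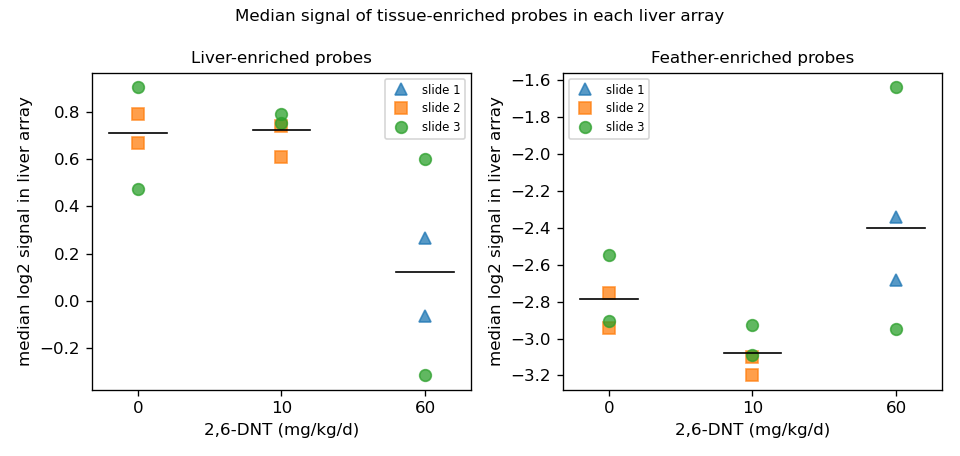
Median log2 signal (vertical axis) of liver-enriched and feather-enriched probes in each liver array, against dose of 2,6-DNT in mg/kg/d (horizontal axis), with symbols for slides and black lines for group means. At 60 mg/kg/d replicate 3 has the lowest liver-enriched median, -0.32, and the highest feather-enriched median, -1.64, and replicate 4 lies near the control arrays at 0.60 and -2.95.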

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

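Apart from the fixed slide block in the liver fit, the tests of the slide and those of feather RNA, of splits by dose and number, of carry-over and of a single split of the birds were chosen after the results had been seen, while the tests of brightness and of other splits were not. Of 84 groups of 4 arrays examined for an array far from the others, 7 had one. About 4.2 would be expected by chance if all had been tested. Groups with a missing spot could not be, namely Contig15086 and Contig3035 in feather pulp at 0 and 60 mg/kg/d. Control feather pulp replicate 4 had 235 saturated probes, more than the rest of its group by 92 or more. In feather pulp at 60 mg/kg/d replicate 4, ERPU0F302FGZKI stood at -1.503 and EQOT2SL02HECDK at -2.58, each far above the other arrays of the group. In feather pulp at 10 mg/kg/d replicate 2, Contig1_25669_R stood at -6.37. In liver at 10 mg/kg/d replicate 2, Contig15086 stood at -6.40 and Contig3035 at -6.56, both below the background threshold. Contig15086 stood at -3.33 in liver at 60 mg/kg/d replicate 3, above the rest of that group by 3.35 or more.

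The response to 60 mg/kg/d differed between liver and feather pulp for 57 probes in the limma interaction, and that to 10 mg/kg/d for 1 probe. The difference between the tissues in log2 fold change at 60 mg/kg/d was 4.46 for EQOT2SL02FKGA5, which was well above background on every array of the 4 groups compared.

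Other splits of the arrays argued against chance for the 605 liver probes at 60 against 0 mg/kg/d: 1 of 35 splits, the real one, gave as many, and the highest other gave 1. The same held for 60 against 10 mg/kg/d in liver, where 1 of 35 splits reached the real 96 and the highest other gave 1, and for the control tissues, where 1 of 35 reached 6118 and the highest other gave 8. Of the 8 splits of the control tissues that part all 4 pairs, 1 reached 6118, and the highest other gave 0. A single split is the smallest share that 35 or 8 splits allow, and these shares were not adjusted over the comparisons. In liver the splits also cannot part the dose of 60 mg/kg/d from slide 1, which held livers of that dose only. For the interaction at 60 mg/kg/d, 4 of 100 regroupings, counting the real labelling, reached 57, and the highest other gave 472. That one kept the liver groups as labelled and regrouped the feather arrays, so the liver change was still in it. Whether structure among the feather arrays added to it was not tested. The drawn regroupings broke up the liver and feather arrays of the same dose and number. Of 35 splits that kept them together, 1 reached 57, and the highest other gave 0. With the replicate block, at the correlation of the real groups, 1 of 35 reached 166, and the highest other gave 7. Chance was not excluded for 10 against 0 mg/kg/d in liver, where 2 of 35 splits reached the real 3, and the split of slide 3 against slide 2 gave 8, the highest other. With the slide as a block this comparison had 2 calls. Nor was it excluded for the interaction at 10 mg/kg/d, where 12 of 100 regroupings reached the real 1 and the highest other gave 15, and 3 of the 35 splits by dose and number reached it, with 2 as the highest other. In feather pulp the real counts were 0, so all 35 splits were as large. The highest others there were 1 for 60 against 0, 10 for 10 against 0 and 173 for 60 against 10 mg/kg/d, and the latter 2 put the arrays of slide 1 against all others.

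The calls in liver at 60 mg/kg/d might reflect the slide in part, because slide 1 held livers of that dose only. Of 500 probes chosen by comparing the 60 mg/kg/d livers of slide 1 with the control livers of slide 2, 70.2% moved the same way within slide 3, which shares no array with that choice, against 62.1% of all probes. The share of the 500 lies between that set for a slide effect alone and that set against it. Across 11061 probes the 2 sets of changes correlated with r = 0.424, where a slide effect alone predicts no correlation. Within slide 3 only 2 arrays of each dose enter, and the spread of this r between arrays is not known, so it does not settle the question. The design confounds slide and dose for slide 1, so the 2 cannot be told apart. The fixed block left 577 calls in the fit of all arrays, against 831 without it, with the slide taken to act alike in both tissues. In the liver fit it left 17. There the median SE of the 605 probes rose from 0.351 to 0.425, and their median change went from 1.63 to 1.48. The lower count thus does not by itself point to the slide. Nor does the small drop in change argue against the slide, as the probes were chosen on the same arrays. A response to the dose stays open as the biological explanation.

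Lower signal of liver-enriched and higher signal of feather-enriched probes in liver at 60 mg/kg/d could come from compressed signals, from the slide or from feather RNA. Compression is argued against on these arrays: compared with other probes of like control signal, the class medians differed by -0.40 and 0.41 on the log2 scale. Without replicate 3 they differed by -0.28 and 0.24, and each value lay outside the middle 95% of 1000 matched draws. The draws resampled probes on the same arrays, so that range does not measure the spread between arrays. The 0.24 also fell short of the size set beforehand against compression. Feather RNA stays open, with 64.8% of the feather-enriched probes above 0 over the group and 53.5%, 64.2%, 84.1% and 43.2% above the control mean in replicates 1 to 4, so a share in all livers alike is not seen, and in replicate 3 whole feather pulp as the only source is argued against: the 100 most abundant had a median of 11.99% of their feather level, near the 11.3% that the class needs, but a 10th percentile of 0.358%, or 0.0315 of the need. Within slide 3 the classes differed from all probes by -0.64 and 0.32, and with the slide as a block in a fit of the array medians by -0.60 ± 0.29 and 0.42 ± 0.34 (SE), but by -0.08 ± 0.18 and -0.18 ± 0.23 without replicate 3, so the slide cannot be told apart. The shift leaned on replicate 3, without which the feather-enriched median was 0.09, and an effect of dose on the liver cells and a changed mix of cells both stay open, untested.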

How the results depend on the processing

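The dose comparisons of a tissue fitted on all arrays with a slide block, the fits with non-uniform spots kept and the tissue classes were chosen after the results had been seen. The slide block in the tissue comparison and the interactions was planned. The directions of the named probes held in every alternative run, but their sizes did not, and signal over background limits the dimmest of them. The normexp offset of 50 by itself shrinks changes of dim signals. With normexp and quantile normalization, the log2 change at 60 mg/kg/d was 2.33 for ERPU0F302FGZKI, 2.35 for Contig1533, -2.92 for EQOT2SL02HECDK and -2.80 for Contig5651, and that at 10 mg/kg/d was 2.60 for EQOT2SL02FKGA5 and 0.97 for EQOT2SL01C4BUX. Where a count moved by more than 1.5 times, the cause was not tested, except that fewer arrays or probes enter some fits. For liver at 60 against 0 mg/kg/d (605 calls), the fixed slide block gave 17, the replicate block by number 315 and the 8 arrays alone 327. Leaving out 1 array gave 208 to 1554. For 10 against 0 (3 calls), normexp gave 6, quantile normalization 5, trend and robust 1, all arrays 34, all arrays with a slide block 59 and the 8 arrays 6; leaving out 1 array gave 1 to 13. For 60 against 10 (96 calls), no filter gave 38, the slide block 3, the replicate block by number 17, all arrays 262, the 8 arrays 6 and contig means 60. Leaving out 1 array gave 4 to 322. In feather pulp at 10 against 0, the slide block gave 8 and all arrays with that block 3, against 0. The tissue comparison (6118 calls) gave 3229 with probes above background on every array, and 6741 with the replicate block. The interaction at 60 mg/kg/d (57 calls) gave 114 with normexp, 97 with quantile and 98 with median scaling, 21 with probes above background on every array and 166 with the replicate block; leaving out 1 array gave 4 to 121. The interaction at 10 mg/kg/d gave 4 with normexp, against 1. With controls split, the correlation of the doses was 0.273 in liver and 0.0422 in feather pulp. With an estimated correlation the adjusted p of the tissue classes was 0.109 and 0.192. The fit with the replicate block moved no other count by over 1.5 times; for 10 against 0 in liver it gave 4 calls, of which 1 was among the 3. Within a tissue that block was by number alone, and numbers within a tissue only name arrays. The alternatives for gene lists were not run, for want of gene names.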

Other observations

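The tests of levels that follow the bird were chosen after the result had been seen. Of 8643 probes above background on at least 10 arrays of each tissue, 107 had liver and feather deviations that correlated above 0.9 over the 12 pairs of arrays with the same dose and number. Random pairing within doses gave a median of 3 and at most 19 such probes in 100 draws. The mean correlation was 0.257, against at most 0.131. The signal of Contig6661, for example, ran from -0.49 to 6.84 in liver and from -0.11 to 6.57 in feather pulp. The widest gap within a pair was at 60 mg/kg/d replicate 1, with -0.09 in liver and 1.18 in feather pulp. Contig14234 was between -1.19 and 0.70 in every liver but that at 10 mg/kg/d replicate 3, where it stood at -7.27, and its feather pulp at -7.85. The sequence of the Contig6661 probe is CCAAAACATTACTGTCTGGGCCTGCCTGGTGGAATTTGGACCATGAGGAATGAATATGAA.

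A candidate explanation is that the numbers mark birds, and that birds differ in the level, or in the sequence under the probe, of these transcripts. With 74 probes chosen on the 0 and 10 mg/kg/d birds only, each 60 mg/kg/d liver correlated best with its own-numbered feather pulp, at 0.627, 0.831, 0.684 and 0.658. The lower correlation of the pairs whose arrays lay on different slides was 0.627, which argues against a shared slide. Of the variance, 1 component held 26.6%, which argues against a single split of the birds, such as sex, behind the 74 probes as a set. Some of the probes could still follow such a split, since the component does not test them singly. Carry-over of RNA between tissues is argued against by the level of abundant tissue-enriched probes. The 74 probes would need 83.7% of the liver signal in feather pulp, or 119.5% of the feather signal in liver. The 10th percentile of the 100 most abundant allowed at most 0.0714% and 0.467% in any pair, so the need was at least 256 times what was allowed. The slope of feather on liver deviations, 0.545 with an SE of 0.0345, did not decide this. Sequence differences under the probes were not tested.

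Of the 3258 contigs with a probe in each orientation, 866 had only the forward and 901 only the reverse probe above background on over 75% of arrays, 847 had both and 644 neither. Across 1412 pairs tested, the liver changes at 60 mg/kg/d correlated between orientations with r = 0.117, and 15 contigs were called in both, 14 of them with the same sign. Across 1802 pairs, the differences between control tissues correlated with r = 0.502. Contigs or probes are not independent replicates.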
